A study of Oryza sativa with 576 samples.

How the data were processed

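Leaf mRNA of rice was sequenced in 576 libraries, 3 for each of 192 groups of condition and sampling. The authors deposited a table of whole-number counts per gene model for each library, and per the labels' protocols RNA was extracted with TRIzol and libraries were made with a directional mRNA kit. Per the submitters' processing notes, STAR and featureCounts were used with the genome build IRGSP-1.0, and their versions and settings, including whether counting used strand, are not given in the sources used here. Each file holds 55986 gene models, of which 55801 carry LOC_Os identifiers and 185 are fgenesh models. All files list the same identifiers, 1699 models had 0 counts in every library, and no files held identical values. Within groups, 576 pairs of replicates were compared by a chi-square test of their counts, and the lowest value per gene was 1.3, in Well-watered2 at day 92 where a library holds 19638 counts. Among pairs of libraries over 2000000 counts the lowest was 1.61 and the median of all pairs 12.6, so every library was kept as its own replicate.

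Groups, days and replicate numbers were taken from the sample titles. Libraries of a drought condition were compared with the well-watered condition that has the same sampling schedule, which is an inference from the schedules. Samplings whose labels carry rewater were left out of the windows and used in the rewater1 comparisons, and those labelled rewater2 entered the comparisons at single samplings. The windows held 5, 5 and 10 samplings in set 1, 5, 3 and 9 in set 2, and 5, 4 and 5 in set 3.

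From the deposited counts, genes were filtered with filterByExpr, normalized with TMM factors and tested with quasi-likelihood models in edgeR 4.0.16 under R 4.3.3. Each model held a mean per condition and sampling, and a window contrast is the mean over days of drought minus well-watered. The other drought condition of the set entered the fit and added to the estimate of spread. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, and a secondary count required a 2-fold change. Rewater1 contrasts were differences of differences, and the comparison of sets was a difference of window 1 responses. Samplings were also tested singly, in fits of the 9 libraries of a set and sampling. CPM values were computed with TMM-scaled library sizes, and log2 CPM values with a prior count of 2.

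Before the data were examined, 20 lists of 193 locus identifiers in another numbering, 14 lists by product text, and a rule for named genes were fixed. The rule took, for each contrast, the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 5 CPM, the same sign at every sampling and a symbol or informative product. The reference table at hand, of assembly ASM3414082v1, paired 1 of the 55986 identifiers with a name, and 0 of the 193 listed identifiers were found in the files. The lists could therefore not be tested and the rule names no gene. In their place, gene groups were defined after the data had been seen: genes called at least 2-fold in a direction in window 1 or 2 of each of the other sets, in either drought condition and without genes that met both directions (drought-rising and drought-falling), or between late and early days in the well-watered plants of both other sets (age-rising and age-falling). The groups tested in set 1 held 2222, 1434, 780 and 1190 genes, those in set 2 held 1004, 988, 781 and 1099, and those in set 3 held 1180, 1300, 1726 and 2448. Some genes belonged to a drought and an age group, for example 311 of the 1434 drought-falling genes of set 1 were also age-falling. Groups were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01 and with an estimated correlation, two-sided, with Benjamini-Hochberg adjustment over the 4 groups of a contrast. Of 72 such tests against well-watered plants, 54 passed with the preset correlation and 17 with the estimated correlation. The 4 identifiers were chosen by another rule, which kept the demand for a mean of at least 5 CPM but not that for a symbol or the 10 largest per contrast. It required a call in 5 contrasts in the same direction at all 22 samplings, which 154 rising and 218 falling genes met. From these, the 2 rising and 2 falling genes with the largest smallest change were taken.

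Alternatives were DESeq2 size factors (RLE) in edgeR, no filter on low counts, a Wald test in DESeq2 1.42.0, the replicate number as a block, an additive model of day and condition, and leaving out each replicate number or each day. Chosen after seeing the data were leaving out libraries under 2000000 counts, leaving out days in doubt (day 32 in window 2 and day 86 in the late window of set 1, days 74 and 80 in the late window of set 2, day 53 in window 1 and day 80 in the late window of set 3), and the first drought condition of each set alone. Other splits of the libraries numbered 21 per contrast with the real one included. Condition labels were redrawn among the libraries of all 3 conditions of each sampling, day labels among all libraries for the age contrasts, and set labels within a day for the well-watered sets. For single samplings, the 10 splits of each 6 libraries were combined over 100 draws.

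The procedures were tested on simulated counts drawn from the real means and library sizes. All genes were given a shared dispersion, without spread particular to a gene, replicate or day. The shares below hold for that setting and may be too favourable for the real libraries. For Drought1 at day 29, a single sampling with 17418 genes, 56.7% of 2-fold and 98.5% of 4-fold changes were recovered, and 6.1% of the calls were false. For the window 1 contrast of Drought1 with 18764 genes, 80.6% of 1.5-fold and 97% of 2-fold changes were recovered, and 3.1% of the calls were false. For the late window of Drought4 with 20259 genes the shares were 85.1% and 97%, with 3.1% false. The depth was at least 3344892 counts in 572 libraries, and the precision of each value is given by the spread of the 3 libraries.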

Results

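Gene expression was measured by mRNA sequencing in leaves of rice (Oryza sativa cultivar Nipponbare) grown under 6 drought conditions and 3 well-watered conditions. The 576 libraries fell into 192 groups of 3 replicates, each group being a condition at a labelled sampling. Well-watered1, Drought1 and Drought2 shared a schedule of 25 samplings that began at day 14 and are called set 1 here. Well-watered2, Drought3 and Drought4 shared 22 samplings from day 29 (set 2), and Well-watered3, Drought5 and Drought6 shared 17 samplings from day 44 (set 3). Drought was started by withholding water, and the matching of each drought condition to a well-watered condition rests on these schedules, since the labels do not state it. Some samplings carry the words rewater1 or rewater2 after the day, which the labels do not explain. The total count per library ranged from 19638 to 30579466 with a median of 9635054.5. All but 4 libraries held at least 3344892 counts. The 3 libraries of Drought2 at day 41 held 552851 to 1143822 counts, and replicate 1 of Well-watered2 at day 92 held 19638, so that values for these groups were less precise. Nothing in the labels says whether the replicates were separate plants, so p-values measure the spread between these libraries, which may be technical.

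The series title names growth-stage-specific effects and time-lagged responses to drought, and the comparisons below follow these questions. Each set was divided at the days that carry a rewater label into window 1 (days 17 to 29, 32 to 44 and 47 to 59 in sets 1, 2 and 3), window 2 (days 32 to 44, 47 to 53 and 62 to 71) and a late window (days 47 to 92, 56 to 92 and 74 to 86). Genes were called with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Because the files pair no identifier with a name or function, responses are described through gene groups defined, after the data had been seen, in the libraries of the other 2 sets. Drought-rising and drought-falling genes changed at least 2-fold against well-watered plants in window 1 or 2 of each of the other sets. Age-rising and age-falling genes changed at least 2-fold between early and late days in the well-watered plants of both other sets. A set's groups therefore share no library with the comparison they are tested in.

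At the first sampling of every set, no gene was called by edgeR between leaves of the drought conditions and well-watered leaves. This held at day 14 in Drought1 or Drought2, at day 29 in Drought3 or Drought4, or at day 44 in Drought5 or Drought6. Unadjusted p lay under 0.05 for 426, 301, 364, 1019, 1683 and 3443 genes in these 6 comparisons. DESeq2 called no gene in Drought1 to Drought4, 20 in Drought5 and 341 in Drought6.

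In set 1, the large change came in Drought2 during window 2. Drought-rising genes rose together there: 1252 of 1856 tested members rose and 131 fell, with a median log2 fold change of 1.03 (camera adjusted p = 7.7e-23, and adjusted p = 3.01e-05 with an estimated correlation). Of 1378 drought-falling genes, 1245 fell and 8 rose, with a median of -1.39 (adjusted p = 7.43e-42, and adjusted p = 7.58e-05 with an estimated correlation). Relative to Well-watered1 on the same day, the mean level of the drought-rising genes lay 0.76 ± 0.10 log2 units higher (SE, n = 3 and 3) at day 35 and 1.33 ± 0.04 higher at day 44. In all, 13879 of 20578 genes were called, 6522 higher and 7357 lower, and the count at day 44 alone was 10200. At day 32 it was 3627, but in fits of 6 libraries 3974 genes differed from Well-watered1 and 1374 from Well-watered2. Without the 3 shallow libraries of day 41 and that sampling, 13389 genes were called.

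Drought1 showed nothing of this kind in window 2. No drought-rising member rose and 2 of 1856 fell, 1 of 1378 drought-falling members rose and 12 fell, and 27 genes were called in all, 7 higher and 20 lower. Neither drought group shifted by camera (adjusted p = 0.0922 and 0.523). The count was between 1 and 81 when a replicate number or a day was left out, 2 without day 32, 74 without the shallow libraries and their day, and 174 without a filter on low counts. At day 32 itself 2520 genes differed between Drought1 and Well-watered1, 1478 higher and 1042 lower, but in fits of 6 libraries 1876 genes differed from Well-watered1 and 110 from Well-watered2.

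During window 1 of set 1, both drought conditions showed small changes. Among 1270 drought-falling genes, 264 fell and 60 rose in Drought1, and 230 fell and 84 rose in Drought2, with medians of -0.10 and -0.07. Among 1427 drought-rising genes, 185 rose and 78 fell in Drought1, and 183 rose and 95 fell in Drought2. These shifts passed camera with the preset correlation (adjusted p = 4.57e-07 and 0.000422 for the falling genes, 0.00587 and 0.0407 for the rising genes). None passed with an estimated correlation (adjusted p = 0.191 in Drought1 and 0.441 in Drought2 for either group). Drought1 differed from Well-watered1 at 2664 of 19087 genes, 116 of them at least 2-fold higher and 88 at least 2-fold lower. Drought2 differed at 2939 genes, 102 and 94 of them by at least 2-fold. Leaving out a replicate number or a day gave 396 to 3110 genes in Drought1 and 729 to 3204 in Drought2, the lowest without replicate 1 in both.

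In set 2, Drought3 and Drought4 responded together in window 1 and parted in window 2. In window 1, 857 of 990 drought-rising genes rose and none fell in Drought3, with a median log2 fold change of 1.28, and 859 rose and none fell in Drought4, with a median of 1.37. Of 965 drought-falling genes, 922 fell in Drought3 and 925 in Drought4, and none rose in either. Camera called all 4 shifts (adjusted p = 3.85e-47 and 1.05e-47 for the rising genes, 1.87e-62 and 2.8e-62 for the falling genes), also with an estimated correlation (adjusted p = 0.00196 in Drought3 and 0.00198 in Drought4). Drought-rising genes lay 0.81 ± 0.15 log2 units above Well-watered2 at day 38 and 2.39 ± 0.08 above it at day 41 in Drought3 (SE, n = 3 and 3). In Drought4 they lay 1.26 ± 0.49 above it at day 38 and 2.31 ± 0.11 at day 41. The windows held 11109 called genes of 20492 in Drought3 (7157 without day 41) and 11481 in Drought4.

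Window 2 of set 2 separated the conditions. In Drought4, 887 of 937 drought-rising genes rose and 9 fell, with a median log2 fold change of 2.69 (camera adjusted p = 1.57e-36, and adjusted p = 1.5e-05 with an estimated correlation). Of 950 drought-falling genes 899 fell and 9 rose, with a median of -2.94 (adjusted p = 3.05e-49, and adjusted p = 1.05e-07 with an estimated correlation). In Drought3 the same groups moved less: 144 of 937 rising members rose and 9 fell, with a median of 0.38 (adjusted p = 6.48e-15, and 0.00234 with an estimated correlation). Of 950 falling members 244 fell and 18 rose, with a median of -0.35 (adjusted p = 7.34e-27, and 9e-06 with an estimated correlation). Called genes numbered 16082 of 20505 in Drought4, 4219 at least 2-fold higher and 3417 at least 2-fold lower, against 1323 in Drought3. The Drought3 count was 184 to 1020 when a replicate number or a day was left out, with the lowest without replicate 2.

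In set 3 the drought conditions responded at different times. Drought5 changed in window 1, where 1042 of 1129 drought-rising genes rose and 1 fell, with a median log2 fold change of 1.72 (camera adjusted p = 3.22e-52, and adjusted p = 5.7e-08 with an estimated correlation). Of 1255 drought-falling genes 1124 fell and 5 rose, with a median of -1.43 (adjusted p = 6.97e-52, and adjusted p = 1.18e-05 with an estimated correlation). Drought6 showed no called member of either group in window 1, where the drought-falling genes had a median of 0.07 (adjusted p = 0.00239, but adjusted p = 0.816 with an estimated correlation). The drought-rising genes lay 1.68 ± 0.18 log2 units above Well-watered3 at day 50 and 2.46 ± 0.12 above it at day 59 in Drought5 (SE, n = 3 and 3), and -0.01 ± 0.07 and 0.06 ± 0.06 from it on the same days in Drought6. In all, 13339 of 20563 genes were called in Drought5, 6941 higher and 6398 lower. In Drought6 edgeR called 0 genes, with 1960 at an unadjusted p under 0.05, and DESeq2 called 11. Leaving out day 53, at which 2923 genes were called in Drought6, raised the window count to 1277.

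In window 2 of set 3 it was Drought6 that stood farther from Well-watered3. There 911 of 1109 drought-rising genes rose and 6 fell, with a median of 1.47 (camera adjusted p = 3.09e-44, and adjusted p = 0.00363 with an estimated correlation). Of 1219 drought-falling genes 971 fell and 20 rose, with a median of -1.14 (adjusted p = 7.07e-41, and adjusted p = 0.00363 with an estimated correlation). In Drought5, 600 of 1109 drought-rising genes rose and 11 fell, with a median of 0.88 (adjusted p = 2.1e-24, but adjusted p = 0.059 with an estimated correlation), while 316 of 1219 drought-falling genes fell and 131 rose (adjusted p = 6.91e-05, but adjusted p = 0.583 with an estimated correlation). The 2 conditions had 11282 and 7437 called genes of 20680. Leaving out a replicate number or a day gave 3292 to 6757 genes in Drought5, the lowest without replicate 1.

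**Figure D1:**
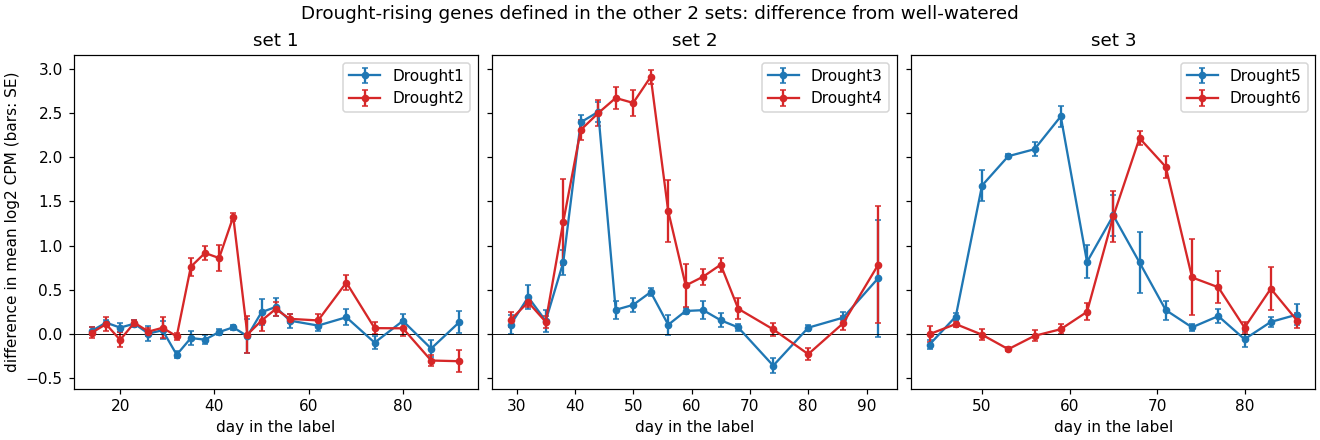
Mean log2 CPM of the drought-rising genes minus that of the well-watered libraries of the same set and day (vertical axis, bars: SE of the difference, 3 libraries per group) against the labelled day (horizontal axis). The difference reached 1.33 at day 44 in Drought2, 2.51 at day 44 in Drought3, 2.91 at day 53 in Drought4, 2.46 at day 59 in Drought5 and 2.21 at day 68 in Drought6, while the wide bars at day 92 of set 2 include the library of 19638 counts.

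Across the sets, 2095 genes rose and 2698 fell in all 5 of these strong responses (Drought2 window 2, Drought3 window 1, Drought4 window 2, Drought5 window 1 and Drought6 window 2) among 19262 genes tested in each. At least 2-fold changes in all 5 were seen for 461 rising and 535 falling genes. Between Drought3 and Drought5 in window 1, which share no library, 3967 genes rose in both and 4235 fell in both, where independent lists would share 1815 and 1740. Of the genes that rose in Drought3, 67 fell in Drought5, and of those that fell in Drought3, 189 rose. Between Drought2 and Drought4 in window 2, 3502 genes rose in both and 4279 fell in both, against 2461 and 2757 for independent lists. There 1274 genes rose in Drought2 and fell in Drought4, and 1615 fell in Drought2 and rose in Drought4.

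The 4 identifiers below are followed as examples, chosen after their values were seen as the 2 with the largest smallest rise and the 2 with the largest smallest fall over the 5 responses. LOC_Os05g31020 rose by a log2 fold change of 4.34 ± 0.16 in Drought2 window 2 (SE, edgeR adjusted p = 5.82e-23), 3.86 ± 0.29 in Drought3 window 1 (adjusted p = 1.31e-12) and 7.46 ± 0.30 in Drought4 window 2 (adjusted p = 2.9e-15). Its level was 1960 ± 433 CPM (SD, n = 3) in Drought4 at day 53 against 6.42 ± 1.48 CPM in Well-watered2. LOC_Os03g17790 rose by 4.12 ± 0.20 in Drought2 window 2 (edgeR adjusted p = 3.64e-19), by 5.84 ± 0.42 in Drought5 window 1 (adjusted p = 4.14e-14) and by 5.34 ± 0.59 in Drought6 window 2 (adjusted p = 2.6e-08). In Drought6 window 1 its log2 fold change was -0.01 ± 0.51 (edgeR adjusted p = 1). LOC_Os05g25370 changed by -4.36 ± 0.14 in Drought2 window 2, -3.61 ± 0.25 in Drought3 window 1 and -5.25 ± 0.19 in Drought5 window 1 (edgeR adjusted p = 1.59e-25, 7.47e-14 and 2.58e-23). Its mean was 0.254 ± 0.242 CPM (SD, n = 3) in Drought2 at day 44 and 54.7 ± 4.33 CPM in Well-watered1. LOC_Os04g21350 changed by -4.60 ± 0.30 in Drought2 window 2 and -5.47 ± 0.28 in Drought4 window 2 (edgeR adjusted p = 2.08e-16 and 1.22e-13). It also fell between early and late days of Well-watered1, by 3.83 on the log2 scale (SE 0.18, edgeR adjusted p = 9.86e-14), and changed by -3.97 in Well-watered2 and -2.76 in Well-watered3 (edgeR adjusted p = 9.22e-08 and 9.64e-07). LOC_Os05g31020 rose over the same days, by 2.63 ± 0.20 in Well-watered1, 2.31 ± 0.14 in Well-watered2 and 0.96 ± 0.21 in Well-watered3 (edgeR adjusted p = 3.55e-10, 1.11e-10 and 0.00125). LOC_Os03g17790 rose there by 1.54, 2.64 and 1.24 (edgeR adjusted p = 0.0024, 0.00133 and 0.0319), and LOC_Os05g25370 rose by 0.98 in Well-watered1 (edgeR adjusted p = 1.55e-06) and was not called in the other sets, with 0.12 in Well-watered2 and -0.31 in Well-watered3 (edgeR adjusted p = 0.304 and 0.0845). Their calls in all 5 responses were a condition of their choice and are no separate result. Reads shared with near-identical genes or antisense transcripts cannot be excluded for the 4 identifiers.

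**Figure D2:**
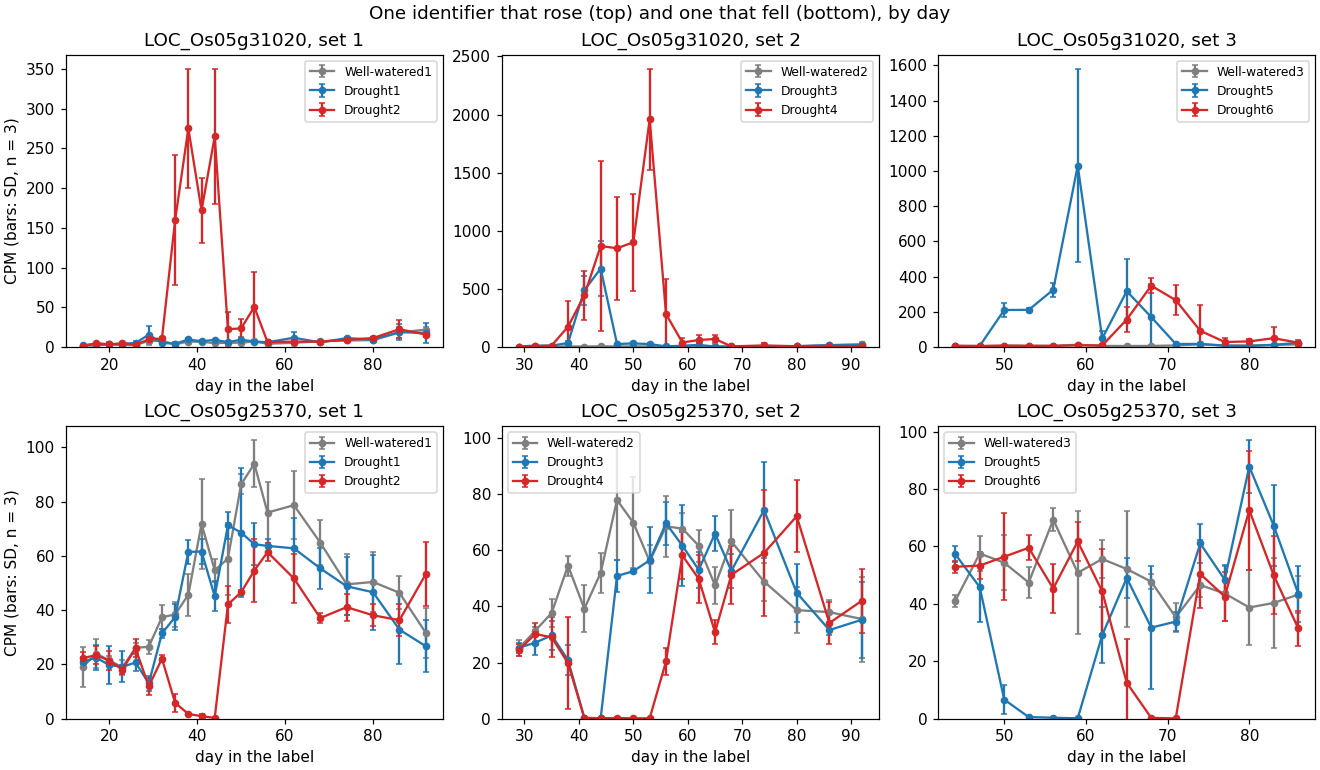
CPM (vertical axes, linear and scaled per panel, bars: SD, 3 libraries per group) of LOC_Os05g31020 and LOC_Os05g25370 against the labelled day (horizontal axes) in the 3 sets. LOC_Os05g31020 reached 1960 CPM in Drought4 at day 53 against 6.42 CPM in Well-watered2, while LOC_Os05g25370 stood at 0.254 CPM in Drought2 at day 44 against 54.7 CPM in Well-watered1.

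The drought conditions of a set were then compared directly. In window 2 of set 1, drought-rising genes stood higher in Drought2 than in Drought1 at 1274 of 1856 members and lower at 120 (camera adjusted p = 7.88e-24, and adjusted p = 2.13e-05 with an estimated correlation). Drought4 exceeded Drought3 in window 2 at 849 of 937 drought-rising genes and fell below it at 17, with a median log2 difference of 2.33 (adjusted p = 1.23e-34, and adjusted p = 2.12e-05 with an estimated correlation). In window 1 of set 3 the order was opposite, with Drought6 below Drought5 at 1045 of 1129 drought-rising genes and above it at 1 (adjusted p = 1.36e-52, and adjusted p = 5.62e-08 with an estimated correlation). By window 2 Drought6 lay above Drought5 at 554 of 1109 of these genes and below at 73 (adjusted p = 1.19e-20, but adjusted p = 0.0502 with an estimated correlation). The whole-transcriptome counts were 13797 genes for Drought2 against Drought1 and 15569 for Drought4 against Drought3 in window 2, and 13423 and 8853 for Drought6 against Drought5 in windows 1 and 2. The last count ranged from 4389 without replicate 2 to 10214 without day 62. In window 1, edgeR called 0 genes between Drought2 and Drought1, with 773 at an unadjusted p under 0.05 and 0 in DESeq2. Between Drought4 and Drought3 it called 0, with 583 at an unadjusted p under 0.05 and 1 in DESeq2.

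Libraries labelled rewater1 were compared with those of the same day without the label, as the difference of the drought effects. The drought groups lay closer to well-watered values under the rewater1 label in Drought5 at day 59 and Drought3 at day 44. The drought-falling genes also did in Drought2 at day 44. Such a difference does not tell whether the drought or the well-watered libraries moved. In Drought5 at day 59, 350 of 1081 drought-rising genes were lower and 42 higher in this difference, with a median of -1.11 (camera adjusted p = 4.03e-11, and adjusted p = 0.0109 with an estimated correlation), and 465 of 1195 drought-falling genes were higher and 38 lower (adjusted p = 3.27e-13, and adjusted p = 0.0242 with an estimated correlation). In Drought3 at day 44, 121 of 985 drought-rising genes were lower and 12 higher, with a median of -0.96, and 249 of 915 drought-falling genes were higher and 1 lower, with a median of 1.36 (adjusted p = 4.98e-15 and 2.32e-28, and adjusted p = 0.00593 and 0.00274 with an estimated correlation). In Drought2 at day 44 the drought-falling genes were higher at 312 of 1341 members and lower at 15 (adjusted p = 5.48e-12, and adjusted p = 0.0181 with an estimated correlation). Its drought-rising genes were lower at 182 of 1754 members and higher at 109 (adjusted p = 0.00253, but adjusted p = 0.131 with an estimated correlation). LOC_Os05g25370 was higher in the difference by 5.78 ± 0.74 on the log2 scale in Drought5 at day 59, by 3.59 ± 0.49 in Drought3 at day 44 and by 3.57 ± 0.94 in Drought6 at day 71 (SE, edgeR adjusted p = 1.98e-05, 0.000418 and 0.0235). It was not called in Drought2 at day 44 (0.81 ± 0.53, edgeR adjusted p = 0.346) or in Drought4 at days 44 and 53 (0.92 ± 0.60 and -1.93 ± 1.18). LOC_Os05g31020 was lower in Drought5 at day 59 (-2.47 ± 0.79, edgeR adjusted p = 0.0238). LOC_Os03g17790 and LOC_Os04g21350 were called in no rewater1 comparison. LOC_Os04g21350, which fell under drought, changed by -1.73 ± 1.14 in Drought5 at day 59.

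In Drought6 at day 71, 233 of 1179 drought-falling genes were higher and 11 lower under rewater1, with a median of 0.82 (camera adjusted p = 1.46e-11, but adjusted p = 0.225 with an estimated correlation). In Drought4 at day 44, where 6438 genes differed from Well-watered2 without the label, 8 of 985 drought-rising genes were lower and 1 of 915 drought-falling genes was higher. The medians were -0.39 and 0.21 (adjusted p = 0.000645 and 0.000619, but adjusted p = 0.181 for both with an estimated correlation). In Drought4 at day 53, 60 of 952 drought-falling genes were higher and 4 lower, with a median of 0.40 (adjusted p = 9.58e-07, but adjusted p = 0.122 with an estimated correlation). Libraries labelled rewater1 still differed from well-watered plants of that label at 9932 genes in Drought5 at day 59 (10282 without the label), 5342 in Drought3 at day 44 (6174) and 9888 in Drought2 at day 44 (10200). The counts were 7106 in Drought4 at day 44 (6438 without the label), 11513 in Drought4 at day 53 (13547) and 4933 in Drought6 at day 71 (7392). Under the rewater2 label at day 44, 9570 genes differed in Drought3, 11131 in Drought4 (6438 without a label) and 7349 in Drought2. Drought-rising genes there lay 1.93 ± 0.17 log2 units above Well-watered2 in Drought3, against 2.51 ± 0.12 without a label, and drought-falling genes -1.29 ± 0.07 against -2.66 ± 0.07 (SE, n = 3 and 3). In Drought4 the drought-rising difference was 2.50 ± 0.05 under rewater2 and 2.50 ± 0.15 without a label. Differences between rewater2 and other samplings were not tested. Genes called in the difference of drought effects for rewater1 numbered 6907 in Drought5 at day 59, 2629 in Drought2 at day 44, 1909 in Drought6 at day 71, 1406 in Drought3 at day 44, 359 in Drought4 at day 53 and 19 in Drought4 at day 44. When single replicate numbers were left out, the counts ranged from 1581 to 8594, 646 to 2130, 291 to 2326, 1 to 2394, 3 to 2194 and 0 to 20 in the same order, the lowest without replicate 2 for Drought5, Drought2, Drought3 and Drought4 at day 53 and without replicate 1 for Drought6. With all libraries and in that order, DESeq2 called 7470, 2765, 2697, 2082, 938 and 79 genes. No gene was called by edgeR in Drought1 at days 29 and 44, Drought2 at day 29, Drought3 at day 53, Drought5 at day 71 or Drought6 at day 59. Unadjusted p lay under 0.05 for 1403, 646, 2766, 1232, 738 and 2647 genes there, and DESeq2 called 6, 0, 202, 48, 4 and 164.

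The question of growth stage was addressed by comparing the window 1 responses of the sets, each the mean of both drought conditions against well-watered plants. The response of set 2 differed from that of set 1 at 9386 of 20648 genes, 4437 higher and 4949 lower, 828 and 1244 of them by at least 2-fold. Set 3 differed from set 2 at 5414 genes and from set 1 at 6251 genes. Because Drought6 showed no gene called by edgeR in window 1, and 11 called by DESeq2, its inclusion lowers the mean response of set 3. With the first drought condition of each set alone, an alternative added after the data had been seen, the 3 counts were 7660, 4651 and 10168. Without a replicate number the set 3 counts were 2566 to 3649 against set 2 and 3135 to 5677 against set 1. Day, age and set cannot be separated in these contrasts, since the windows lie at different ages. The strength of drought cannot be separated from them either. In window 1 the drought-rising genes had medians of 0.12 in Drought1 and 0.09 in Drought2, against 1.28 in Drought3 and 1.37 in Drought4.

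In well-watered plants, early and late days were compared, which differ in harvest date as well as age. Late days differed from early days at 15194 of 19550 genes in Well-watered1 (days 80 to 92 against 14 to 20), at 13284 of 19212 in Well-watered2 (80 to 92 against 29 to 35) and at 10252 of 19341 in Well-watered3 (80 to 86 against 44 to 50). At least 2-fold changes numbered 2627 higher and 3138 lower genes in Well-watered1, 2068 and 3221 in Well-watered2, and 899 and 1307 in Well-watered3. In the well-watered plants of all 3 sets, 730 genes met the definition of age-rising and 1066 that of age-falling. Any 2 of the 3 definitions of an age group share a set, so their overlap is partly built in. An age score, the mean log2 CPM of the age-rising genes minus that of the age-falling genes, went from -4.97 ± 0.12 (SD, n = 3) at day 14 to 1.30 ± 0.22 at day 92 in Well-watered1. The Well-watered3 count was 5978 without replicate 1, 7067 without replicate 2 and 10303 without replicate 3.

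Well-watered plants of the 3 sets were also compared with each other on days 44, 47, 50, 53 and 56. By edgeR, Well-watered2 differed from Well-watered1 at 91 of 19215 genes, Well-watered3 from Well-watered2 at 1027 and Well-watered3 from Well-watered1 at 1777. The first count was 242 with the DESeq2 Wald test and lower without a filter on low counts. Between 0 and 65, 96 and 375, and 134 and 1629 genes were called when a replicate number was left out.

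In the late windows, the age groups shifted in 5 of the 6 drought conditions by camera with the preset correlation, while with an estimated correlation only the age-falling genes of Drought4 passed. In Drought4, 887 of 1095 age-falling genes stood higher than in Well-watered2 and 5 lower, with a median log2 fold change of 0.66 (camera adjusted p = 1.41e-48, and adjusted p = 0.0155 with an estimated correlation). Of 780 age-rising genes 417 stood lower and 51 higher, with a median of -0.44 (adjusted p = 2.1e-22, but adjusted p = 0.102 with an estimated correlation). Drought2 showed the same direction, with 411 of 1190 age-falling genes higher and 35 lower and 284 of 778 age-rising genes lower and 15 higher (adjusted p = 1.61e-17 and 4.01e-13, but adjusted p = 0.126 for both with an estimated correlation). In Drought1 the direction was opposite, with 244 of 778 age-rising genes higher and 1 lower and 251 of 1190 age-falling genes lower and 20 higher (adjusted p = 9.25e-18 and 3.05e-14, but adjusted p = 0.11 and 0.197 with an estimated correlation). Directly compared, Drought2 lay below Drought1 at 479 of 778 age-rising genes and above at 4, and above at 684 of 1190 age-falling genes and below at 18 (adjusted p = 6.53e-36 and 1.89e-38, and adjusted p = 0.00754 and 0.0117 with an estimated correlation).

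The age score followed the same course by sampling. In Drought4 the difference from Well-watered2 was -1.45 ± 0.24 log2 units (SE, n = 3 and 3) at day 80 and -1.96 ± 0.38 at day 86. Drought4 was lower at 8 of the 9 late samplings, Drought2 at 9 of 10, Drought3 at 6 of 9, Drought5 at 4 of 5, Drought6 at 3 of 5 and Drought1 at 1 of 10. In that order the mean differences were -1.07, -0.51, -0.36, -0.41, 0.02 and 0.42. In Drought3, 256 of 1095 age-falling genes were higher and 1 lower, and 131 of 780 age-rising genes were lower and 25 higher (camera adjusted p = 3.49e-23 and 1.97e-09, but adjusted p = 0.178 and 0.519 with an estimated correlation). In Drought5, 667 of 2313 age-falling genes were higher and 31 lower, and 381 of 1725 age-rising genes were lower and 130 higher (adjusted p = 3.53e-20 and 8.21e-06, but adjusted p = 0.121 and 0.218 with an estimated correlation). Drought6 showed no shift of either age group by camera (adjusted p = 0.226 and 0.136), with 457 of 2313 age-falling genes higher and 317 lower.

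**Figure D3:**
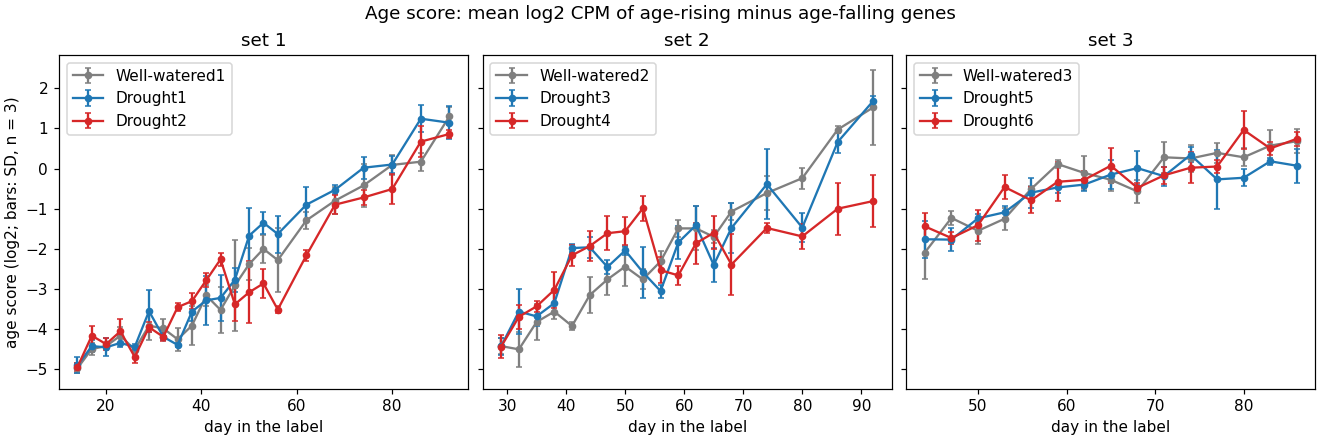
Age score (vertical axis, mean log2 CPM of age-rising minus age-falling genes, bars: SD, 3 libraries per group) against the labelled day (horizontal axis) for the well-watered and drought conditions of each set. In set 1 the well-watered score went from -4.97 at day 14 to 1.30 at day 92, and in set 2 the difference of Drought4 from Well-watered2 was -1.96 at day 86.

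Of the drought groups in the late window, the drought-rising genes were higher in Drought4 at 392 of 849 members and lower at 46, with a median of 0.44 (camera adjusted p = 6.47e-14, but adjusted p = 0.102 with an estimated correlation). In Drought6 they were higher at 366 of 938 members and lower at 37 (adjusted p = 1.56e-09, but adjusted p = 0.293 with an estimated correlation). Of 1746 drought-rising genes, 284 were higher and 80 lower in Drought1 and 312 and 135 in Drought2 (adjusted p = 0.00088 and 0.000252, but adjusted p = 0.212 and 0.142 with an estimated correlation). No shift was called in Drought3 and Drought5 (adjusted p = 0.109 and 0.224). The drought-falling genes differed in direction between conditions, and none of their shifts passed with an estimated correlation. They were higher at 323 of 1229 members and lower at 58 in Drought5 (adjusted p = 9.51e-10, but adjusted p = 0.121 with an estimated correlation), and higher at 123 of 984 and lower at 61 in Drought3 (0.0385, but 0.703). They were lower at 478 of 1433 members and higher at 175 in Drought2 (9.79e-05, but 0.142), and lower at 311 of 1229 and higher at 163 in Drought6 (0.0158, but 0.789). In Drought4 346 of 984 were lower and 253 higher (0.0165, but 0.583), with a median of -0.08 and a mean of 0.03, and in Drought1 121 of 1433 were lower and 201 higher (0.921).

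Counts of called genes in the late window were 3363 in Drought1, 5696 in Drought2, 1869 in Drought3, 9191 in Drought4, 4170 in Drought5 and 7560 in Drought6. For Drought4, 51% of the called genes were higher, and 63.5% with DESeq2 size factors. Single late samplings also held many called genes: 9236 differed at day 74 in Drought3, 6736 at day 86 in Drought2, 1699 at day 86 in Drought1 and 8729 at day 80 in Drought6. Without the days in doubt (day 86 in set 1, days 74 and 80 in set 2, day 80 in set 3) the counts were 1850 in Drought1, 6172 in Drought2, 1332 in Drought3, 10068 in Drought4, 3103 in Drought5 and 7197 in Drought6. Without 1 replicate number the counts fell as low as 3382 in Drought2 (replicate 3), 443 in Drought3 (replicate 3), 6110 in Drought4 (replicate 2), 209 in Drought5 (replicate 2) and 4054 in Drought6 (replicate 1), and without replicates 1, 2 and 3 in turn the Drought1 count was 816, 643 and 3891. Direct comparison gave 7060 genes between Drought2 and Drought1, 6090 between Drought4 and Drought3 and 5410 between Drought6 and Drought5, the last falling to 2738 without day 80. Without replicate 3 the first was 3985 and the last 2063, and without replicate 2 the second was 2580.

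At single samplings, at least 100 genes were called in 7 of 25 samplings in Drought1 and 19 of 25 in Drought2. In set 2 this held for 6 of 22 samplings in Drought3 and 19 of 22 in Drought4, and in set 3 for 10 of 17 in Drought5 and 9 of 17 in Drought6. Drought4 passed from 13547 genes at day 53 to 4123 at day 56 and 397 at day 74, but 4345, 3248 and 4960 genes were called at days 80, 86 and 92. Of these days, 80 is in doubt and 92 includes the library of 19638 counts. Drought3 passed from 6174 at day 44 to 65 at day 47, with 9236 at day 74. In Drought5 the count went from 10282 at day 59 to 1199 at day 62. Counts simulated for Drought1 at day 29 had 3 libraries per group and a shared dispersion for all genes. In these, 56.7% of 2-fold and 6% of 1.5-fold changes were recovered. DESeq2 gave at least 100 genes in 12 samplings of Drought1 and 15 of Drought3, while for Drought1 edgeR gave 5 with replicate number in the model and 2, 4 and 2 without replicates 1, 2 and 3.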

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

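The splits of libraries in this part were planned, and the comparison with the first drought condition of each set alone was chosen only after the results were seen.

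The drought effect differed between samplings labelled rewater1 and the same day without that label, by the interaction test, in 6 of 12 comparisons. In Drought5 at day 59 there were 6907 genes; 1 of 21 splits gave as many, the real one, with 6382 as the highest other. In Drought6 at day 71 there were 1909 genes; 1 of 21 splits gave as many and the highest other was 146. In Drought2 at day 44 there were 2629 genes and 2 of 21 splits gave as many, the highest other being 7565. In Drought3 at day 44 there were 1406 and 2 of 21 splits gave as many, the highest other being 1593. In Drought4 there were 19 genes at day 44 (2 of 21 splits, highest other 724) and 359 at day 53 (3 of 21 splits, highest other 15311). The redrawn libraries of a sampling included well-watered plants and both drought conditions, so a split can turn a drought effect into a difference of drought effects. The splits are therefore no reference without change, and nothing about chance is read from them for these 6 comparisons.

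The window 1 drought response differed between sets by the same kind of test. The counts were 9386 genes for set 2 against set 1, 5414 for set 3 against set 2 and 6251 for set 3 against set 1. For each, 1 of 21 splits gave as many genes, the real one, with 1277, 135 and 2 as the highest others. Since these are also differences of drought effects, nothing about chance is read from the splits. With the first drought condition of each set alone the counts were 7660, 4651 and 10168.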

How the results depend on the processing

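Leaving out libraries under 2000000 counts, leaving out the days in doubt, using the first drought condition of each set alone, and the gene groups with their estimated correlation were chosen only after the results were seen. The gene lists fixed beforehand gave no value under any setting, since 0 of their 193 identifiers were found in the files. Of 54 summary counts, DESeq2 size factors kept 54 within 1.5 times, the replicate block 52, no filter on low counts 49 and the DESeq2 Wald test 41. The additive model kept 22 of 27. Leaving out replicate 1, 2 or 3 kept 31, 32 and 40 of 54, and most that moved fell, with fewer libraries tested. The 128 counts at single samplings were less stable: 127 stayed within 1.5 times with DESeq2 size factors, 79 without a filter, 55 with the DESeq2 Wald test, and 47, 50 and 54 without replicate 1, 2 or 3. With DESeq2 size factors the higher share of called genes went from 51% to 63.5% in the late window of Drought4 and from 53.4% to 65.9% for Drought4 against Drought3. All 140 alternative values of the 4 identifiers kept their direction and call, with a largest adjusted p of 0.000119. They had been chosen for large changes in these same contrasts, which favours this. The cause of the changes below was not tested.

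Libraries share a replicate number across groups, but the numbers pair them weakly at most. Deviations of libraries with the same number had a median correlation of 0.026, over 0.1 in 206 of 576 pairs (35.8%). For different numbers the median was -0.016, with 344 of 1152 pairs (29.9%) over 0.1. With the replicate number as a block the count was 9 for rewater1 in Drought4 at day 44 and 30 in Drought6 at day 59, and it moved none of the other 52 summary counts by over 1.5 times. Of the 128 counts at single samplings, 89 stayed within 1.5 times under the block.

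The DESeq2 Wald test gave 113 genes in Drought1 window 2, 11 in Drought6 window 1, 1 for Drought4 against Drought3 in window 1 and 242 for Well-watered2 against Well-watered1. For rewater1 it gave 6 in Drought1 and 202 in Drought2 at day 29, 48 in Drought3 and 938 in Drought4 at day 53, 79 in Drought4 at day 44, 4 in Drought5 at day 71 and 164 in Drought6 at day 59. Samplings with at least 100 genes numbered 12 in Drought1 and 15 in Drought3. The additive model gave 5 genes in Drought1 window 2, 1523 in the late window of Drought1, 1161 in that of Drought3, 2724 in that of Drought5, and 1 for Drought2 against Drought1 in window 1. Without a filter the counts were 174 in Drought1 window 2, 29 for Well-watered2 against Well-watered1, and 13, 2 and 2 for rewater1 in Drought2 at day 29, Drought3 at day 53 and Drought6 at day 59. Without libraries under 2000000 counts Drought1 window 2 held 74. Without the days in doubt the counts were 2 in Drought1 window 2, 1850 in the late window of Drought1, 1277 in Drought6 window 1 and 2738 for Drought6 against Drought5 in the late window. The first drought condition of each set alone gave 10168 for set 3 against set 1.

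Leaving out a replicate number or a day gave these ranges. Window 1 held 396 to 3110 genes in Drought1, 729 to 3204 in Drought2, 7157 to 11266 in Drought3 and 0 to 1277 in Drought6. Window 2 held 1 to 81 in Drought1, 184 to 1020 in Drought3, 3292 to 6757 in Drought5 and 4389 to 10214 for Drought6 against Drought5. The late window held 643 to 4503 in Drought1, 3382 to 6368 in Drought2, 443 to 3367 in Drought3, 6110 to 9860 in Drought4, 209 to 4974 in Drought5 and 4054 to 7807 in Drought6. It held 3985 to 7991 for Drought2 against Drought1, 2580 to 8806 for Drought4 against Drought3 and 2063 to 6798 for Drought6 against Drought5. Leaving out a replicate number, rewater1 gave 646 to 2130 in Drought2, 1 to 2394 in Drought3 and 0 to 20 in Drought4 at day 44, 3 to 2194 in Drought4 at day 53, 1581 to 8594 in Drought5 at day 59 and 291 to 2326 in Drought6 at day 71. Set 3 held 2566 to 3649 against set 2 and 3135 to 5677 against set 1. Age in Well-watered3 gave 5978 to 10303, and the well-watered sets 0 to 65, 96 to 375 and 134 to 1629. Drought1 had 2 to 4 samplings with at least 100 genes. The lowest value came without replicate 1 for window 1 of Drought1 and Drought2, without replicate 2 for the late windows of Drought1 and Drought5, and without replicate 3 for that of Drought3.

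Single days that moved a count by over 1.5 times were days 23, 26 and 29 in Drought1 window 1 (1558, 1501 and 1260 genes without them), days 20 and 29 in Drought2 window 1 (1681 and 1309) and day 41 in Drought3 window 1 (7157). In Drought1 window 2 they were days 32, 35, 41 and 44 (2, 3, 74 and 81), in Drought3 window 2 days 47 and 50 (275 and 364) and in Drought5 window 2 days 62 and 65 (4927 and 4840). In Drought6 window 1 the count was 1277 without day 53 and 1 without day 50, 56 or 59. In the late window they were day 86 in Drought1 (1850), day 92 in Drought3 (3367) and days 77 and 86 in Drought5 (2720 and 2489). Between Drought6 and Drought5 they were days 68 and 71 in window 2 (5813 and 5213) and days 80 and 83 in the late window (2738 and 3078).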

Other observations

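All tests of the shared late profile and of continued drying and a younger profile were chosen only after the results were seen, while the tests with other control libraries for the age score and for day 32 and the splits of libraries were planned. The test of displaced controls for the shared profile was divided into 3 parts, and the test of a younger profile was made per condition with an exact test added, after a first outcome that had met the looser version was known. Well-watered groups of set 2 were then dropped from the profile test because they share a control with it.

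Late changes were compared between sets for a single pair of conditions, Drought2 and Drought4. Between Drought2 and Drought4 in the late window, which share no library, 1708 genes rose in both and 1816 fell in both, where independent lists would share 573 and 686. Only 34 genes rose in Drought2 and fell in Drought4. In the window 1 responses of set 2, age-falling genes fell as well, at 697 of 1099 members in Drought3 and 703 in Drought4 (camera adjusted p = 3.43e-15 and 3.4e-16, and adjusted p = 0.0343 and 0.0283 with an estimated correlation), while 121 and 131 rose. Other strong responses did not show this with an estimated correlation: 663 fell and 262 rose in Drought2 window 2 (adjusted p = 2.54e-05, but adjusted p = 0.339 with an estimated correlation), and 652 fell and 269 rose in Drought4 window 2 (adjusted p = 6.48e-07, but adjusted p = 0.228 with an estimated correlation). In Drought5 window 1, 894 fell and 810 rose (adjusted p = 0.39), and in Drought6 window 2, 798 fell and 656 rose (adjusted p = 0.322). In the late window of set 3, drought-falling genes were lower in Drought6 than in Drought5 at 488 of 1229 members and higher at 24 (adjusted p = 1.79e-19, and adjusted p = 0.0223 with an estimated correlation).

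The profiles of Drought3 at day 74, Drought2 at day 86 and Drought6 at day 80 against well-watered plants correlated across 12336 genes at r = 0.90, 0.90 and 0.86, genes not being independent replicates. Renewed drying that repeats the earlier drought profile is argued against, since the highest correlation with the same condition's own drought profile was 0.093. The drought profiles of Drought3 at day 41 and Drought2 at day 44 correlated at 0.87. Those 2 days are close in age, while the late profiles were set against days 41, 44 and 68. Drying with another profile in older leaves is therefore not excluded. For Drought3 at day 74, 8243 genes were called against Well-watered2, 4282 against Well-watered1 and 3080 against Well-watered3. A displaced control group as the whole account is therefore argued against for Drought3. A contribution stays open, since the count was lower against the other controls. Set against neighbouring days, these correlated with the profile themselves, at 0.7 in Well-watered1 and 0.64 in Well-watered3. For Drought6 at least 7512 genes were called against the other sets' controls, but the controls of day 80 may be displaced themselves. Set against neighbouring days, Well-watered3 at day 80 correlated with the Drought3 profile at -0.7 and Well-watered1 at -0.49. A contribution of displaced controls therefore stays open for Drought6. It also stays open for Drought2 at day 86, with 6 genes against Well-watered2 and 4663 against Well-watered3. A state that well-watered plants also enter may account for the profile. A well-watered group set against its neighbouring days correlated with it at up to 0.75 (Well-watered3 at day 83), with 6 of 36 groups over 0.5 and 6 under -0.5. A correlation gives no size. A score, the mean log2 CPM of the genes most raised in the Drought3 profile minus that of the most lowered, was 3.04 in Drought3 at day 74. It was 2.1 in Drought6 at day 80, 1.93 in Drought2 at day 86 and 1.97 in Well-watered3 at day 59, the highest well-watered value. In Well-watered3 at day 83 it was 0.44. The score's genes came from Drought3, which raises its value there. Harvest conditions on single days were not tested.

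Lower age scores of Drought2 and Drought4 in the late window are the second pattern, with mean differences of -0.51 and -1.07. The scores were also lower on average in Drought3 and Drought5, by mean differences of -0.36 and -0.41. The explanations below were examined for Drought2 and Drought4 only. Drying that goes on at the strength of window 2 is argued against, since the median change of the drought-rising genes was at most 0.16 of that in window 2. Milder drying, or drying on single days, is not excluded. In the late window of Drought4, 392 of 849 drought-rising genes were higher and 46 lower, with a median of 0.44. Against the other set's controls the mean difference was -0.49 in Drought2 and -1.18 in Drought4. The score's genes were chosen in part from the late days of those same controls, which favours a negative difference. Nothing is therefore concluded about displaced controls. Slower development may be a candidate explanation but cannot be told apart from a change of the score's genes alone: over genes outside the groups the nearest well-watered day lay 3 days earlier in Drought2 and 9.4 days earlier in Drought4, by an exact two-sided sign-flip test with p = 0.38 for each.

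At day 32 Drought1 differed from Well-watered1 at 1876 genes in a comparison of these 6 libraries. A displaced Well-watered1 group and a difference of the Drought1 libraries cannot be told apart, since 338 genes were called between Well-watered2 and Well-watered1 and 110 between Drought1 and Well-watered2 on that day, both too many to exclude and too few to single out either.

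Among the 21 splits per contrast, 1 of 21, the real one, gave as large a count for 15 of 18 window comparisons with well-watered plants. Labels were redrawn among all 3 conditions of a sampling, so the splits are no reference without change for a single pair of conditions, and nothing about chance is read from them for the window comparisons. The real count and the highest other were 2664 and 0 for Drought1 and 2939 and 0 for Drought2 in window 1, 13879 and 2981 for Drought2 in window 2, and 3363 and 619 for Drought1 and 5696 and 471 for Drought2 in the late window. In set 2 they were 11109 and 1 for Drought3 and 11481 and 1871 for Drought4 in window 1, 16082 and 2272 for Drought4 in window 2, and 1869 and 1611 for Drought3 and 9191 and 446 for Drought4 in the late window. In set 3 they were 13339 and 1077 for Drought5 in window 1, 7437 and 13 for Drought5 and 11282 and 1746 for Drought6 in window 2, and 4170 and 2 for Drought5 and 7560 and 1 for Drought6 in the late window. For Drought1 window 2 (27 genes), 3 of 21 splits gave as many, with 1749 as the highest other, and for Drought3 window 2 (1323 genes) 2 of 21 with 3007. For Drought6 window 1 (0 genes in edgeR, 1960 at an unadjusted p under 0.05 and 11 in DESeq2) 21 of 21 gave as many, which a count of 0 fixes beforehand, and the highest other was 3620. The redrawn libraries included the other drought condition of the set, with 13879 genes in Drought2 window 2, 16082 in Drought4 window 2 and 13339 in Drought5 window 1, a structure that can give the splits with 1749, 3007 and 3620 genes by construction.

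Between the drought conditions of a set, 1 of 21 splits gave as many genes as the real one in 7 of 9 comparisons, and for the same reason nothing about chance is read from them. Real count and highest other were 13797 and 1544 (window 2) and 7060 and 178 (late) in set 1, 15569 and 0 (window 2) and 6090 and 0 (late) in set 2, and 13423 and 3, 8853 and 325, and 5410 and 1 in windows 1, 2 and late of set 3. In window 1 of sets 1 and 2, where edgeR called 0 genes, with 773 and 583 at an unadjusted p under 0.05 and 0 and 1 in DESeq2, 21 of 21 splits gave as many, which a count of 0 fixes beforehand, and the highest others were 2 and 1. For the 6 rewater1 comparisons with 0 genes in edgeR, 21 of 21 splits gave as many for the same reason, and the highest others were 0 and 3 for Drought1 at days 29 and 44, 9 for Drought2 at day 29, 12560 for Drought3 at day 53, 777 for Drought5 at day 71 and 9388 for Drought6 at day 59. Unadjusted p lay under 0.05 for 1403, 646, 2766, 1232, 738 and 2647 genes there, and DESeq2 called 6, 0, 202, 48, 4 and 164. The redrawn libraries again included the other drought condition, so nothing about chance is read from these splits.

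For age in Well-watered1, Well-watered2 and Well-watered3, 1 of 21 splits was as large (15194, 13284 and 10252 genes, highest others 11060, 227 and 1). These splits redrew libraries across days and so broke up those that share a day, and nothing about chance is read from them. For the well-watered sets on the same days, 91, 1027 and 1777 genes were called. The highest others were 27, 0 and 79, with 1 of 21 splits as large. These splits broke up the libraries of a set and day, which may be technical replicates, so nothing about chance is read from them either. Samplings with at least 100 genes numbered 7, 19, 6, 19, 10 and 9 in Drought1 to Drought6. The highest of the other splits were 4, 6, 3, 6, 4 and 4, with 1 of 100 as large. These splits cover only the spread between libraries, which may be technical, so chance differences between plants are not excluded. In Drought1 the number was 2, 4 and 2 without replicates 1, 2 and 3.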
